A study of Homo sapiens with 15 samples.

How the data were processed

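Total RNA of 15 human samples was measured on Affymetrix Human Genome U133 arrays (the A array), 1 array per sample. Per the labels, 3 samples each came from HeyA8 with vehicle, HeyA8 with 10 uM norepinephrine, SKOV3-ip1 with vehicle, SKOV3-ip1 with 10 uM norepinephrine, and normal ovary given as a control. The exposure time, the culture conditions and the origin of the normal ovary RNA were not given in the sources used here. Every column of values matched 1 sample, no pair of arrays was identical, and replicates were not pooled.

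The deposited values were linear probe set intensities, normalized between arrays before deposition as far as the values show. MAS5 was named per the submitters' processing notes, with no version and no scaling target. The median intensity per array was 48.4 to 50.5, the 75th percentile 145 to 159, the 90th percentile 402 to 449, and the highest intensity 13510 to 16851. No intensity was lower than 7.12, and in 101 of 111075 combinations of probe set and group the values of the 3 arrays were exactly equal. Such even quantiles and such a narrow lower end are not typical of MAS5 signals alone, so the summary method is not settled, and the intensities were used on the scale as deposited. No detection calls were used here. With 3 arrays per group, the number of arrays limits the precision.

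The platform annotation named 1 gene for 19065 of the 22283 probe sets, several for 1043 and none for 2107, and 68 were array controls. Of the probe sets with 1 gene, 19053 were matched by Entrez identifier to the reference gene names, and 0 symbols changed. Intensities were taken as log2(intensity + 16) with no further normalization. Each of 11963 genes was represented by 1 probe set naming that gene alone. A probe set marked as cross-hybridising (ending in _x_at) was taken only where the gene had no other, and then the one with the highest mean over all arrays was used. A gene was tested if at least 3 arrays of the fit lay above that array's 40th percentile.

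Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend on mean intensity). P-values were adjusted by Benjamini-Hochberg over all genes tested, and genes passed at an adjusted p under 0.05. For named genes under the 40th percentile on every array of 1 group, the size of the change depends on the pseudocount and was taken as a bound, chosen after seeing the data: "at least N-fold" sets the mean of the brighter group against the mean 40th percentile of the dimmer group's arrays, on the log2(intensity + 16) scale. This held for 5 named genes with norepinephrine in each line, 26 between the untreated lines, and 25 and 27 in HeyA8 and SKOV3-ip1 against normal ovary. Where only the mean of a group lay under the mean 40th percentile of its arrays, the size was left out of the report. The 12 cell line arrays shared 1 fit for norepinephrine against control in each line, for the average of both effects, for the difference between both effects (HeyA8 minus SKOV3-ip1), and for HeyA8 control against SKOV3-ip1 control. That fit tested 8454 genes and had 8 residual degrees of freedom per gene and 13.0 prior ones. The 9 control arrays shared a second fit for each line against normal ovary, with 8473 genes, 6 residual degrees of freedom and 12.4 prior ones. The p-values measure only the spread between these samples, since the labels do not say whether replicates were separate cultures or, for ovary, separate donors.

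Overlaps of calls between the lines were tested with Fisher's exact test or set beside 50 simulated pairs of unchanged groups against the same 3 normal ovary arrays. Ratios of 3' to 5' control probe sets and spike-in intensities were compared with two-sided exact permutation tests, whose smallest possible p with 3 against 3 arrays is 0.1. Plots were drawn with matplotlib 3.10.9.

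The comparisons, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 10 highest and 10 lowest log2 fold changes (5 and 5 for the difference between lines) among genes that passed and whose arrays of both groups did not overlap, in both lines for the average, and without this condition for the difference. It added up to 4 members of each list that passed, by size of change, or the 2 with the smallest p where none passed. In the norepinephrine comparisons it added, among others, FOS, FOSB, JUNB, EGR1, NR4A1, NR4A2, CREM, PER1, IL6, CXCL8, VEGFA, MMP2, MMP9, PLAUR, SRC and PTK2, of which PER1 is not analysed here. The text gives those of the resulting genes that describe each group best, and genes whose called probe sets pointed in opposite directions are named as uncertain.

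The 24 gene lists were cAMP/CREB immediate-early targets, adrenergic receptors and cAMP signalling, inflammatory cytokines and chemokines, angiogenesis factors, matrix proteases and inhibitors, focal adhesion and Src signalling, epithelial markers, mesenchymal markers, ovarian carcinoma markers, ovarian stroma and steroidogenic markers, smooth muscle and endothelial markers, immune cell markers, blood and erythroid markers, cell cycle (G2/M and S phase), cholesterol biosynthesis, glycolysis and hypoxia targets, unfolded protein and amino acid stress response, heat shock response, interferon response, p53 targets and apoptosis, TGF-beta targets, oxidative phosphorylation, ribosomal proteins, and histones. Lists were tested with camera, which compares a list's genes with all other genes, at a preset inter-gene correlation of 0.01 and again with the correlation estimated per list, adjusted over the lists of a comparison. fry, which tests whether the genes of a list move one way on balance and compares them with no other genes, was an alternative. Over 168 list tests, the median, the mean and the direction of the test differed in sign in 25, none of which passed.

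The replicate numbers in the titles were checked as pairs by correlating the deviations of same-numbered arrays from their group means, across genes. These correlations lay over 0.1 in all 3 pairs only between SKOV3-ip1 control and normal ovary (0.13, 0.16 and 0.24). A cell line and a tissue share no donor, so this pairing is a hint from the data and not a design given by the labels, and the replicate number as a block was an alternative.

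The scripts were tested on simulated data with 100 genes changed by 0.5 and 100 changed by 1 on the log2 scale. For norepinephrine in HeyA8, 87% and 100% of these were recovered, with 5.08% of calls false. For norepinephrine in SKOV3-ip1 the shares were 87% and 99% (5.58% false), for the average 99% and 100% (2.93%), and for the difference between lines 55% and 99% (4.35%). For HeyA8 control against SKOV3-ip1 control they were 88% and 100% (3.59%), for HeyA8 against normal ovary 88% and 100% (3.09%), and for SKOV3-ip1 against normal ovary 83% and 99% (5.21%).

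Alternatives covered quantile normalization, median centring, a smaller pseudocount of 1 and a larger one, no filter, a filter at the 60th percentile, the mean of all probe sets of a gene, every probe set on its own, eBayes without trend, robust eBayes, all 15 arrays in 1 fit, only the groups compared, a 1.5-fold minimum, the replicate block, leaving out each array in turn, the estimated correlation, and fry. Log2 intensities with no pseudocount were added after seeing the data. Array control probe sets were left out of the tests, and probe sets naming no gene or several genes were only counted.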

Results

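Gene expression was measured as array intensity in HeyA8, a human ovarian carcinoma line, in SKOV3-ip1, a derivative of the ovarian carcinoma line SKOV3 obtained from ascites after intraperitoneal growth in mice, and in normal ovary. Each line had 3 arrays with vehicle (control) and 3 with 10 uM norepinephrine, the sympathetic neurotransmitter that acts on adrenergic receptors, and normal ovary had 3 control arrays. Median intensity per array was 48.4 to 50.5. Within groups, arrays correlated at 0.993 to 0.998 across genes, and the median gene had an SD of 0.074 (HeyA8 with norepinephrine) to 0.104 (SKOV3-ip1 control) on the log2 scale. The first principal component held 45.9% of the variance and set SKOV3-ip1 apart, and the second held 44.8% and set normal ovary apart from HeyA8. The third held 3.6% and separated norepinephrine from control arrays in both lines. Changes are given as log2 fold changes ± SE with limma's adjusted p, 3 arrays per group, and levels as mean ± SD of log2(intensity + 16).

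The comparison of norepinephrine with vehicle in HeyA8 asked which genes respond to the neurotransmitter in this line. CDKN1C, which encodes the cyclin-dependent kinase inhibitor p57, rose 17.3-fold, from 5.70 ± 0.13 to 9.81 ± 0.24 (log2 fold change 4.12 ± 0.10, adjusted p = 1.25e-17). That control level lay close to its arrays' 40th percentiles (5.64 to 5.65), so the size depends in part on the pseudocount. Follistatin (FST), which binds activins, rose by 3.42 ± 0.12 (1.08e-14), and PLPP3, a phosphatase of lysophosphatidic acid and related lipids, rose by 3.37 ± 0.08 (1.25e-17). IL1A, an inflammatory cytokine, fell by 2.15 ± 0.09 (7.9e-14), and the AP-1 subunits JUN and FOSL1 changed by -2.01 ± 0.10 (1.66e-12) and -1.50 ± 0.10 (1.3e-10). Of 8454 genes tested, 258 rose and 232 fell, and 112 and 67 of these changed at least 1.5-fold.

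Among the cAMP/CREB immediate-early targets, genes that cAMP signalling is known to induce, 13 of 28 tested members rose, 6 fell and 9 did not pass (14 rose and 6 fell adjusted over the list alone). The adjusted p of the list was 1.01e-07. DUSP1, a phosphatase of MAP kinases, rose by 2.13 ± 0.09, the kinase SGK1 by 2.07 ± 0.09 and the neurotrophin BDNF by 1.93 ± 0.09. Higher too was CREM, a cAMP-responsive transcription factor (1.51 ± 0.09, 1.55e-11). Among well-known immediate-early genes, NR4A1 (-0.07 ± 0.08, 0.876) did not pass in this line. FOS (0.994) and NR4A2 (0.332) lay under the 40th percentile on every array of both groups, so a response of these could not be read. JUNB (0.915) and FOSB (0.501) lay on average under it in the control group and EGR1 (0.976) barely above it, so that these did not pass is no evidence of a missing response. With the mean of its 3 probe sets, of which 1 had the direction just given, NR4A1 turned to 0.19 and passed (adjusted p 0.0476). Further genes with large rises were AVPI1 (2.71 ± 0.09), a vasopressin-induced gene, and NID2 (at least 3.73-fold, 8.86e-15), a basement membrane protein. They also included GPRC5A (2.14 ± 0.09), an orphan receptor. Large falls included HMGA2 (-1.96 ± 0.08), an architectural chromatin protein, and TRIB1 (-1.66 ± 0.12), a pseudokinase. The growth factor FGF5 (-1.53 ± 0.10), the transcription factors MAFF (-1.49 ± 0.11) and KLF2 (-1.45 ± 0.12), and DUSP6 (-1.30 ± 0.07), a phosphatase of ERK, fell as well.

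Inflammatory cytokines and chemokines fell as a group in HeyA8: 7 of 17 members fell, 2 rose and 8 did not pass (9 and 2 adjusted over the list alone; adjusted p 7.6e-05). The chemokine CXCL8 fell by 1.13 ± 0.10 (3.63e-08), IL1B by 1.09 ± 0.11 and CXCL3 by 0.90 ± 0.12, while IL6 rose by 0.88 ± 0.18 (0.00241). Cholesterol biosynthesis rose, with 5 of 16 members higher, 0 lower and 11 not passing (6 and 0 adjusted over the list alone; 9.7e-07). The rises included INSIG1 (1.05 ± 0.10), a regulator of sterol sensing, and the enzymes IDI1 (0.99 ± 0.09) and HMGCS1 (0.88 ± 0.12). Glycolysis and hypoxia targets rose, with 6 of 30 higher, 0 lower and 24 not passing (6 and 0 adjusted over the list alone; 1.14e-05). Among them were DDIT4 (at least 4.04-fold), an inhibitor of mTORC1, and the glucose transporters SLC2A1 (0.79 ± 0.10) and SLC2A3 (at least 1.22-fold). Focal adhesion and Src signalling fell as a list (0.00919) through small shifts, since 1 of 29 members fell, 0 rose and 28 did not pass (1 and 0 adjusted over the list alone). That member was PXN, which encodes paxillin, at -0.36 ± 0.08 (0.00712, and 0.0506 without HeyA8 control 1). SRC changed by -0.24 ± 0.11 (0.293) and PTK2, the focal adhesion kinase, by -0.14 ± 0.10 (0.692). These lists and the cAMP/CREB list were also called with an estimated correlation (adjusted p 0.00725 to 0.0452).

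The preset correlation alone called 4 further lists in HeyA8. Of the TGF-beta targets, 5 of 17 rose, 1 fell and 11 did not pass (5 and 2 adjusted over the list alone; 0.00766, adjusted p = 0.0704 with an estimated correlation). Rises were those of ID3 (1.98 ± 0.15), a repressor of bHLH transcription factors, INHBA (1.47 ± 0.09), a subunit of activin, and BAMBI (0.91 ± 0.10), a decoy receptor. Angiogenesis factors had 6 of 20 higher, 1 lower and 13 not passing (7 and 3 adjusted over the list alone; 0.0124, adjusted p = 0.124 with an estimated correlation). Endothelin-1 (EDN1) rose by 1.97 ± 0.09, FGF2 by 0.90 ± 0.08 and adrenomedullin (ADM) by 0.81 ± 0.09, and the receptor EPHA2 fell by 0.67 ± 0.08. VEGFA rose by 0.47 ± 0.13 (0.0285), a call that ended without HeyA8 control 1 (0.163) or 3 (0.173) or norepinephrine 2 (0.152) or 3 (0.0713). It also ended with the mean of all probe sets (0.293), with the larger pseudocount (0.0848), and with all 15 arrays in 1 fit (0.0518). The unfolded protein and amino acid stress response had 5 of 27 higher, 2 lower and 20 not passing (5 and 2 adjusted over the list alone; 0.0319, adjusted p = 0.077 with an estimated correlation, and 0.0696 without HeyA8 norepinephrine 3). The amino acid transporter SLC7A5 rose by 0.48 ± 0.07 and PPP1R15A, which encodes a phosphatase subunit, fell by 0.74 ± 0.08. Oxidative phosphorylation shifted upward as a list with 0 of 42 members passing (0.00919, adjusted p = 0.163 with an estimated correlation).

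No call was made in HeyA8 for the other 15 lists. Adrenergic receptors and cAMP signalling had 0 of 29 members passing, smooth muscle and endothelial markers 0 of 9, immune cell markers 0 of 7, blood and erythroid markers 0 of 4 and ribosomal proteins 0 of 37. Among p53 targets and apoptosis, 4 of 20 rose and 4 fell. Values were PLK2 0.67 ± 0.12, GADD45B 0.62 ± 0.08, GADD45A -0.68 ± 0.10 and BCL2L1 -0.66 ± 0.10. Of matrix proteases and inhibitors, 1 of 22 rose and 1 fell, the latter being the urokinase PLAU (-1.08 ± 0.07). MMP2 (0.01 ± 0.09, 0.986), MMP9 (-0.05 ± 0.09, 0.937) and the urokinase receptor PLAUR (-0.26 ± 0.13, 0.416) did not pass. Epithelial markers had 2 of 15 higher, CD24 (1.32 ± 0.13) and keratin KRT7 (0.61 ± 0.10), and 0 lower. Mesenchymal markers had 1 of 15 higher (TWIST1, 0.54 ± 0.09) and 1 lower (ZEB1, -0.54 ± 0.10). Ovarian carcinoma markers had 1 of 18 higher and 1 lower, and ovarian stroma and steroidogenic markers 1 of 5 higher (INHBA) and 1 lower (WT1, -0.58 ± 0.08). Cell cycle genes had 1 of 38 higher and 0 lower, and heat shock response 2 of 15 higher and 1 lower, with the chaperone DNAJB4 at 0.77 ± 0.12. Interferon response had 2 of 26 higher and 0 lower, and histones 1 of 9 higher and 0 lower.

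**Figure D1:**
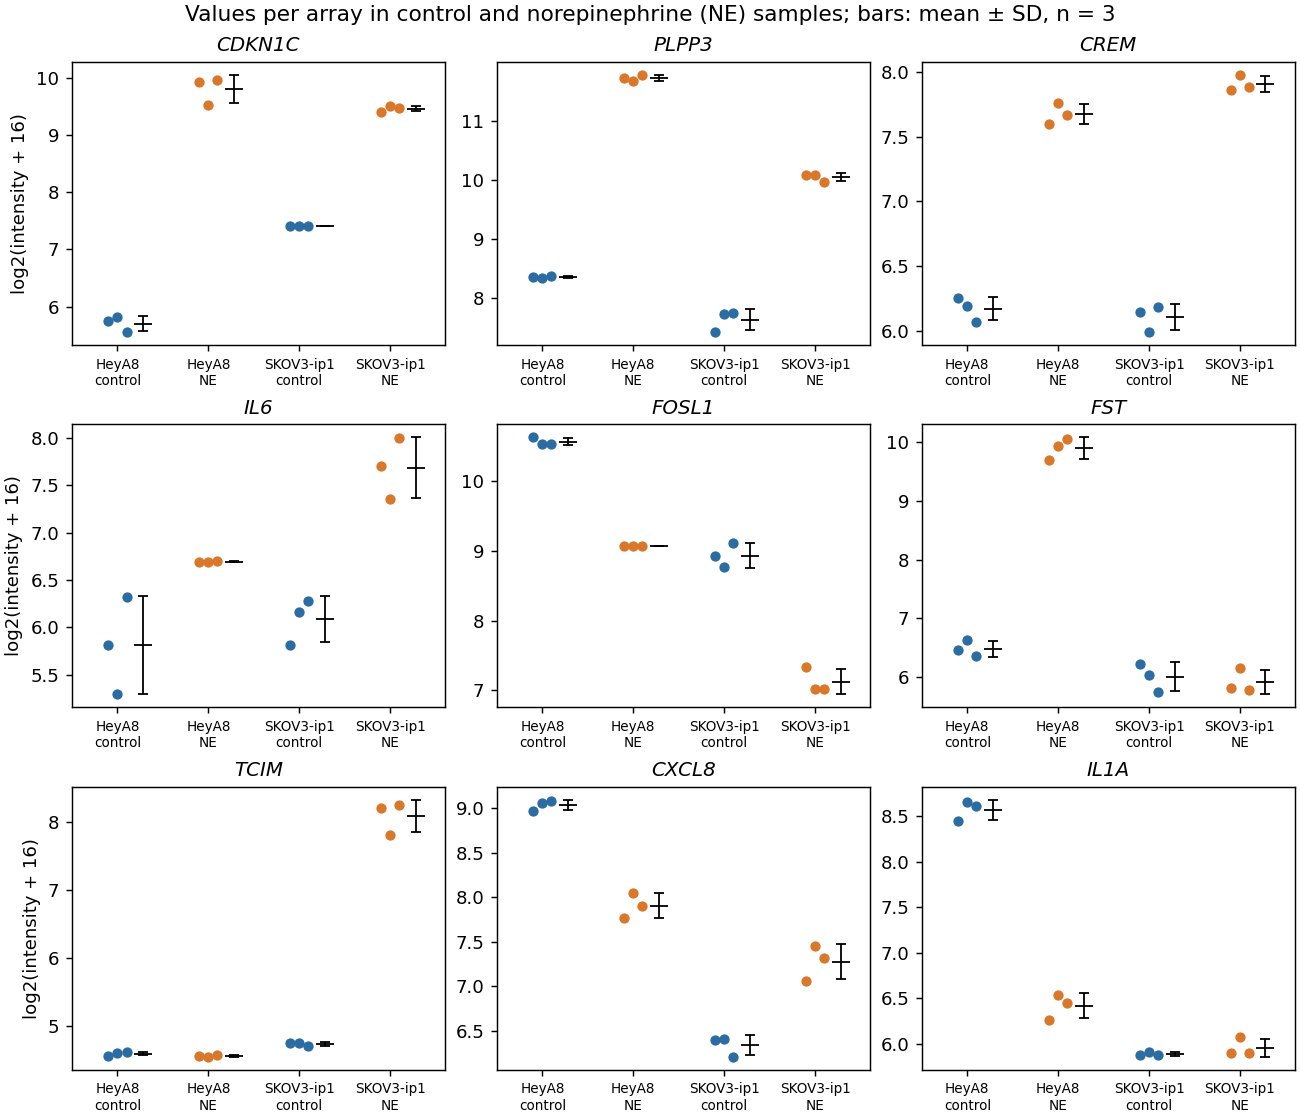
Levels of 9 genes in the 12 cell line arrays, as log2(intensity + 16), with 1 point per array (control blue, norepinephrine orange) and the mean ± SD of 3 arrays. CDKN1C moved from 5.70 to 9.81 in HeyA8 and reached 9.47 in SKOV3-ip1, while CXCL8 fell from 9.04 to 7.91 in HeyA8 and rose from 6.34 to 7.28 in SKOV3-ip1.

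The same question was asked of SKOV3-ip1. TCIM, a transcriptional and immune response regulator, rose at least 5.41-fold to 8.08 ± 0.24 (adjusted p = 1.72e-17), from under the 40th percentile on every control array, and CD55, which protects cells from complement, rose by 2.78 ± 0.08 (1.27e-16). The adhesion protein FLRT3 (at least 4.84-fold), the cAMP phosphodiesterase PDE4D (2.37 ± 0.15) and the activin subunit INHBA (9e-14) rose at least 4-fold. So did the Wnt antagonist DKK1 (2.17 ± 0.07), the kinase SIK1 (2.16 ± 0.12) and the DNA-binding protein ARID5B (2.12 ± 0.10). FOSL1 fell by 1.81 ± 0.10 (7.33e-12) and the transcription factor KLF10 by 1.48 ± 0.10. TXNIP, which binds thioredoxin, fell by 1.16 ± 0.09, and PLK1, a kinase of mitosis, by 1.06 ± 0.09 (9.69e-09). Of 8454 genes, 627 rose and 542 fell, and 173 and 49 of these changed at least 1.5-fold. In a fit of these 6 arrays alone, 411 rose and 298 fell.

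cAMP/CREB immediate-early targets rose in SKOV3-ip1, with 18 of 28 members higher, 3 lower and 7 not passing (19 and 4 adjusted over the list alone; 1.39e-11, and 0.00177 with an estimated correlation). CREM rose by 1.81 ± 0.09 (1.19e-12) and ID4, a repressor of bHLH transcription factors, by 1.77 ± 0.12. Rises were also seen for the nuclear receptor NR4A2 (at least 1.95-fold, 1.54e-08) and FOS (0.62 ± 0.11, 0.000494). JUNB fell by 0.32 ± 0.10 (0.0339), a call that ended without SKOV3-ip1 control 1 (0.142) or 3 (0.0505) or norepinephrine 3 (0.143). It also ended with the smaller pseudocount (0.0661) or none (0.0702), with no filter (0.0518), and with only the groups compared (0.0705). NR4A1 changed by -0.04 ± 0.08 (0.807), EGR1 by -0.02 ± 0.11 (0.942) and FOSB by 0.03 ± 0.09 (0.863), and did not pass. Of the 3 probe sets of NR4A1, 1 had this direction. With the mean of all probe sets, NR4A1 rose on average over both lines (0.17, adjusted p 0.00509).

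The unfolded protein and amino acid stress response rose, with 11 of 27 members higher, 1 lower and 15 not passing (12 and 1 adjusted over the list alone; 1.29e-06, and 0.00402 with an estimated correlation). HERPUD1, a component of endoplasmic reticulum-associated degradation, rose by 1.40 ± 0.12, the chaperone DNAJB9 by 1.20 ± 0.13, the tryptophan-tRNA synthetase WARS1 by 1.07 ± 0.08 and the cystine transporter SLC7A11 by 0.94 ± 0.11. Cell cycle genes fell, with 13 of 38 members lower, 2 higher and 23 not passing (16 and 2 adjusted over the list alone; 5.25e-05, and 0.00878 with an estimated correlation). Besides PLK1, the spindle checkpoint kinase BUB1 fell by 0.74 ± 0.09 and the proliferation antigen MKI67 by 0.62 ± 0.08, while CDC6, which licenses replication origins, rose by 1.05 ± 0.09. Among the 21 mitotic genes of the list 11 fell and 0 rose (median -0.33), and among the 17 S-phase genes 2 fell and 2 rose (median -0.06). The direction of RRM2, an S-phase gene of the list, was uncertain, since its called probe sets pointed in opposite directions.

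**Figure D2:**
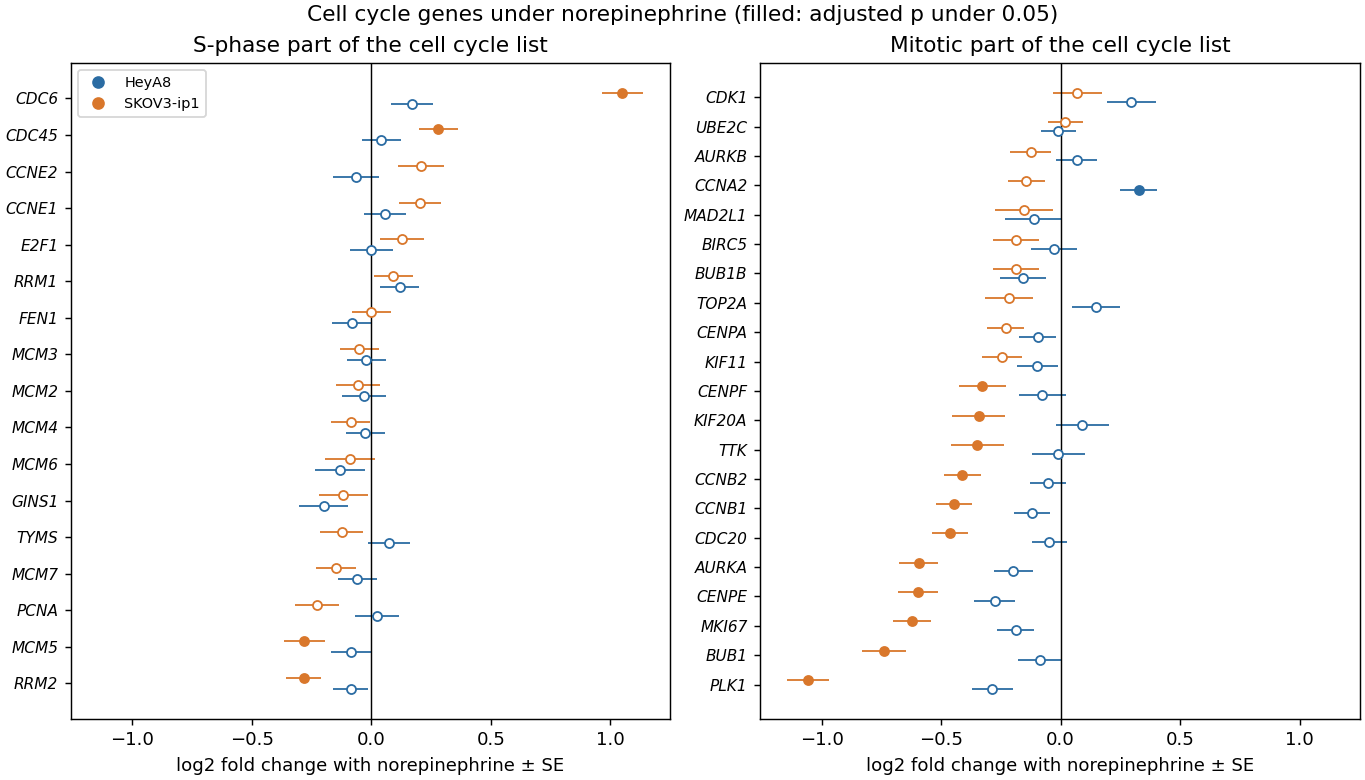
Log2 fold change with norepinephrine ± SE of the 17 S-phase and 21 mitotic genes of the cell cycle list in HeyA8 and SKOV3-ip1, filled where the gene passed at an adjusted p under 0.05. In SKOV3-ip1 the medians were -0.06 for S phase and -0.33 for mitosis, and in HeyA8 they were -0.02 and -0.08.

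With the preset correlation alone, 4 further lists were called in SKOV3-ip1. TGF-beta targets had 7 of 17 higher, 2 lower and 8 not passing (9 and 3 adjusted over the list alone; 0.00359, adjusted p = 0.0712 with an estimated correlation). INHBA, ID3 (1.39 ± 0.15) and BAMBI (0.74 ± 0.10) were among the rises. Glycolysis and hypoxia targets had 7 of 30 higher, 0 lower and 23 not passing (7 and 2 adjusted over the list alone; 0.00445, adjusted p = 0.118 with an estimated correlation). Rises included DDIT4 (1.83 ± 0.11), the hypoxia-induced NDRG1 (1.44 ± 0.12) and the carbonic anhydrase CA12 (0.77 ± 0.11). Cholesterol biosynthesis had 3 of 16 higher, 0 lower and 13 not passing (3 and 0 adjusted over the list alone; 0.0255, adjusted p = 0.245 with an estimated correlation, and 0.0715 without SKOV3-ip1 control 1). The 3 were INSIG1 (0.92 ± 0.10), EBP (0.75 ± 0.10) and IDI1 (0.45 ± 0.09). Oxidative phosphorylation had 3 of 42 higher, 0 lower and 39 not passing (3 and 0 adjusted over the list alone; 0.0229, adjusted p = 0.245 with an estimated correlation, 0.0647 without SKOV3-ip1 control 2, 0.112 with quantile normalization and 0.0656 with the filter at the 60th percentile). NDUFA1 rose by 0.39 ± 0.08.

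Other lists were not called in SKOV3-ip1. Inflammatory cytokines and chemokines had 4 of 17 higher, 3 lower and 10 not passing (6 and 5 adjusted over the list alone). IL6 rose by 1.60 ± 0.18 (1.2e-06), CXCL1 by 1.20 ± 0.12, CXCL8 by 0.94 ± 0.10 (6.6e-07) and CXCL2 by 0.81 ± 0.09. Angiogenesis factors had 6 of 20 higher and 4 lower. The Notch ligand JAG1 (1.28 ± 0.13), EDN1 (0.82 ± 0.09) and the co-receptor NRP2 (0.74 ± 0.10) rose, and VEGFA (0.14 ± 0.13, 0.538) did not pass. Adrenergic receptors and cAMP signalling had 3 of 29 higher and 1 lower. Rises were the G protein subunit GNAI1 at 1.64 ± 0.12 and the protein kinase A anchor AKAP12 at 0.95 ± 0.08. Of matrix proteases and inhibitors, 0 of 22 rose and 2 fell, PLAU (-1.04 ± 0.07) and MMP2 (-0.30 ± 0.09, 0.0201; 0.135 without SKOV3-ip1 control 1, 0.0526 without norepinephrine 2 and 0.0722 without norepinephrine 3). MMP9 (-0.14 ± 0.09, 0.327) and PLAUR (0.12 ± 0.13, 0.609) did not pass. Of focal adhesion and Src signalling, 1 of 29 rose and 4 fell, and neither SRC (-0.23 ± 0.11, 0.155) nor PTK2 (0.31 ± 0.10, 0.0548) passed. Epithelial markers had 3 of 15 higher, among them CD24 (0.98 ± 0.13) and plakoglobin JUP (0.81 ± 0.09), and 1 lower, KRT19 (-0.41 ± 0.09). p53 targets and apoptosis had 2 of 20 higher, the antiproliferative BTG1 (1.91 ± 0.11) and PMAIP1 (0.68 ± 0.11), and 2 lower, GADD45A (-0.79 ± 0.10) and GADD45B (-0.48 ± 0.08). Ovarian carcinoma markers had 3 of 18 higher, with MECOM at 0.64 ± 0.08. Heat shock response had 3 of 15 lower, with HSPH1 at -0.49 ± 0.07, interferon response 2 of 26 higher and 2 lower, with ISG15 at 0.73 ± 0.09. Ribosomal proteins had 3 of 37 higher and 1 lower, histones 1 of 9 higher (H2BC12, 0.44 ± 0.10), ovarian stroma and steroidogenic markers 1 of 5 higher (INHBA), and immune cell markers 1 of 7 lower. Mesenchymal markers (15), smooth muscle and endothelial markers (9) and blood and erythroid markers (4) had 0 members passing.

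**Figure D3:**
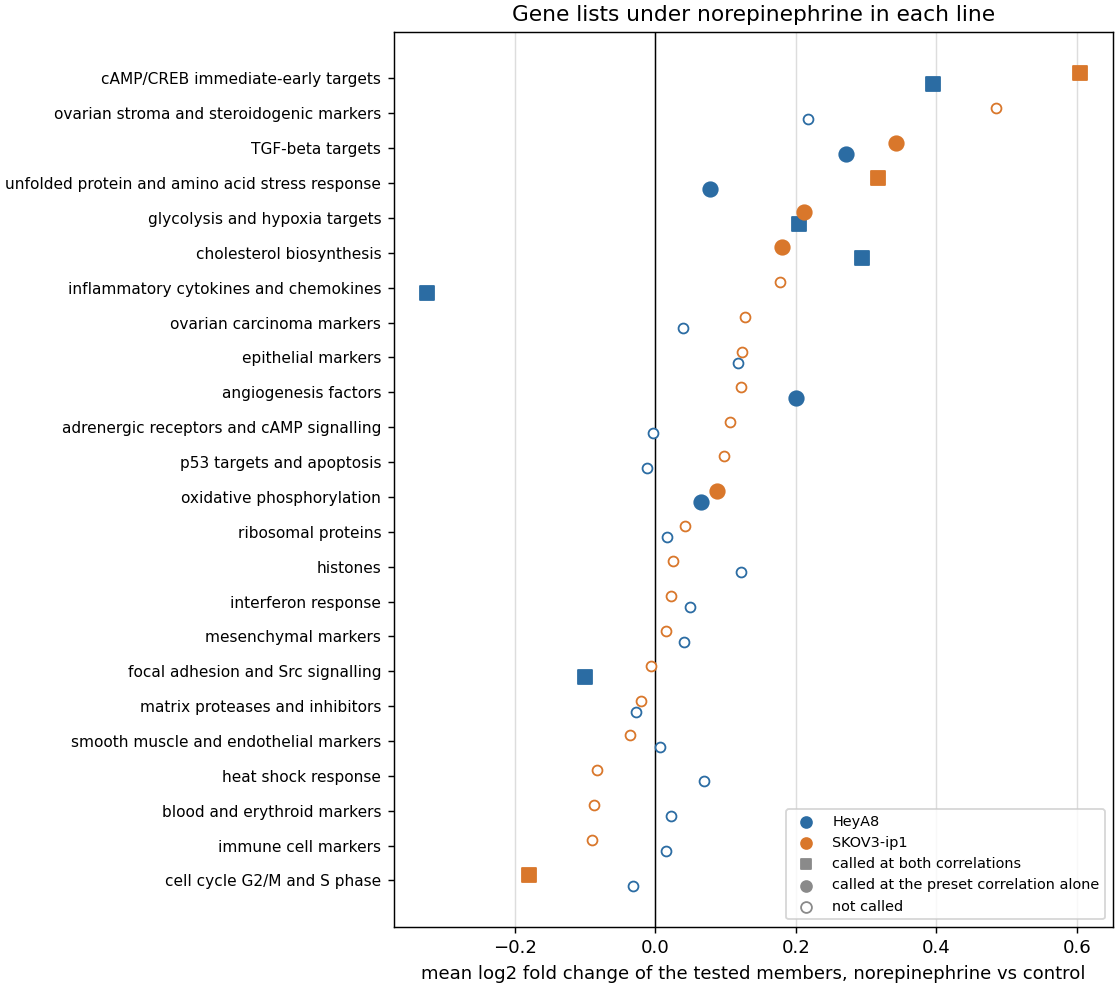
Mean log2 fold change with norepinephrine of the members of each of the 24 gene lists, in HeyA8 (blue) and SKOV3-ip1 (orange). Squares mark lists called with both correlations, filled circles lists called with the preset correlation alone, and open circles lists not called. The cAMP/CREB list was called with both correlations in both lines, with adjusted p of 1.01e-07 and 1.39e-11 at the preset one.

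As a check of RNA quality beside the norepinephrine comparisons, the log2 ratio of 3' to 5' ACTB probe sets was higher with norepinephrine by 0.129 in HeyA8 (exact p = 0.1) and by 0.144 in SKOV3-ip1 (exact p = 0.3). That of GAPDH changed by -0.0254 (exact p = 0.7) and by 0.0868 (exact p = 0.3). The bioB spike differed by -0.0358 and 0.0926 (exact p = 1 and 0.4) and the cre spike by -0.033 and -0.0957 (exact p = 0.3 and 0.4).

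The average of both effects and the overlap of calls described what the lines shared. PLPP3 (average 2.89 ± 0.06, adjusted p = 4.66e-19) and CDKN1C (3.09 ± 0.07, 2.54e-18) rose in both lines. So did AVPI1 (2.27 ± 0.06), CD55 (1.90 ± 0.06), INHBA (2.88e-15), DUSP1 (1.76 ± 0.06), CREM (1.66 ± 0.06) and SGK1 (1.66 ± 0.06). FOSL1 (-1.65 ± 0.07, 3.95e-14), KLF10 (-1.35 ± 0.07) and PLAU (-1.06 ± 0.05) fell in both. The 3 SKOV3-ip1 control intensities of CDKN1C were exactly equal, a tie of unknown origin on which its effect in SKOV3-ip1, its average and its difference between the lines rest in part. Its size in HeyA8, and with it the average, also depends in part on the pseudocount. On average, JUN changed by -1.40 ± 0.07 and HMGA2 by -1.34 ± 0.06. IL6 rose by 1.24 ± 0.13 (2.04e-07), while CXCL8, which moved in opposite directions, averaged -0.10 ± 0.07 (0.43). VEGFA averaged 0.31 (0.0253), a call that ended without HeyA8 control 1 (0.0751) or 3 (0.0793), HeyA8 norepinephrine 2 (0.0727), SKOV3-ip1 control 3 (0.0654) or SKOV3-ip1 norepinephrine 3 (0.0818), and with the mean of all probe sets (0.136). At least 2-fold changes in the same direction in both lines were found for 20 genes. Those outside the rule for named genes, given after their values were seen, were CHMP1B, TENT5A, TFAP2A and TM4SF1, all higher.

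Between the lines, 127 genes rose in both (19.1 expected of independent lists, odds ratio 14.9, Fisher's exact p = 6.28e-77) and 63 fell in both (14.9 expected, odds ratio 6.02, p = 5.22e-24). Of 223 genes called in both lines, 33 moved in opposite directions, 12 up in HeyA8 and down in SKOV3-ip1 and 21 the other way. Independent lists of the same sizes would share about as many in opposite directions, so this count alone is no excess. Log2 fold changes of the lines correlated at r = 0.414 across genes, which are not independent replicates; the lines had separate control arrays. On average 631 genes were higher and 636 lower, of which 125 and 28 changed at least 1.5-fold.

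For the average, 5 lists were called with both correlations. The fall of the cell cycle list among them came mainly from SKOV3-ip1, where the mitotic median was -0.33 against -0.08 in HeyA8. The direction of RRM2 in this list was uncertain on average as well. cAMP/CREB targets had 16 of 28 higher, 5 lower and 7 not passing (17 and 5 adjusted over the list alone; 2.31e-10 and 0.00263). Glycolysis and hypoxia targets had 10 of 30 higher and 0 lower (10 and 0 adjusted over the list alone; 1.55e-05 and 0.0268), and cholesterol biosynthesis 6 of 16 higher and 0 lower (6 and 0 adjusted over the list alone; 2.12e-05 and 0.0491). The unfolded protein and amino acid stress response had 10 of 27 higher and 2 lower (12 and 2 adjusted over the list alone; 2.12e-05 and 0.00979). Cell cycle genes had 11 of 38 lower, among them PLK1 (-0.67 ± 0.06), CENPE (-0.44 ± 0.06) and BUB1 (-0.41 ± 0.06), and 1 higher, CDC6 (14 and 3 adjusted over the list alone; 0.00166 and 0.0268). Called with the preset correlation alone were TGF-beta targets (6 of 17 higher, 2 lower; 8 and 3 adjusted over the list alone; 0.00276, adjusted p = 0.0533 with an estimated correlation) and oxidative phosphorylation (5 of 42 higher, 0 lower; 5 and 0 adjusted over the list alone; 0.00166, adjusted p = 0.131 with an estimated correlation). So were angiogenesis factors (8 of 20 higher, 2 lower; 9 and 2 adjusted over the list alone; 0.0264, adjusted p = 0.153 with an estimated correlation, and 0.053 without SKOV3-ip1 control 1).

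**Figure D4:**
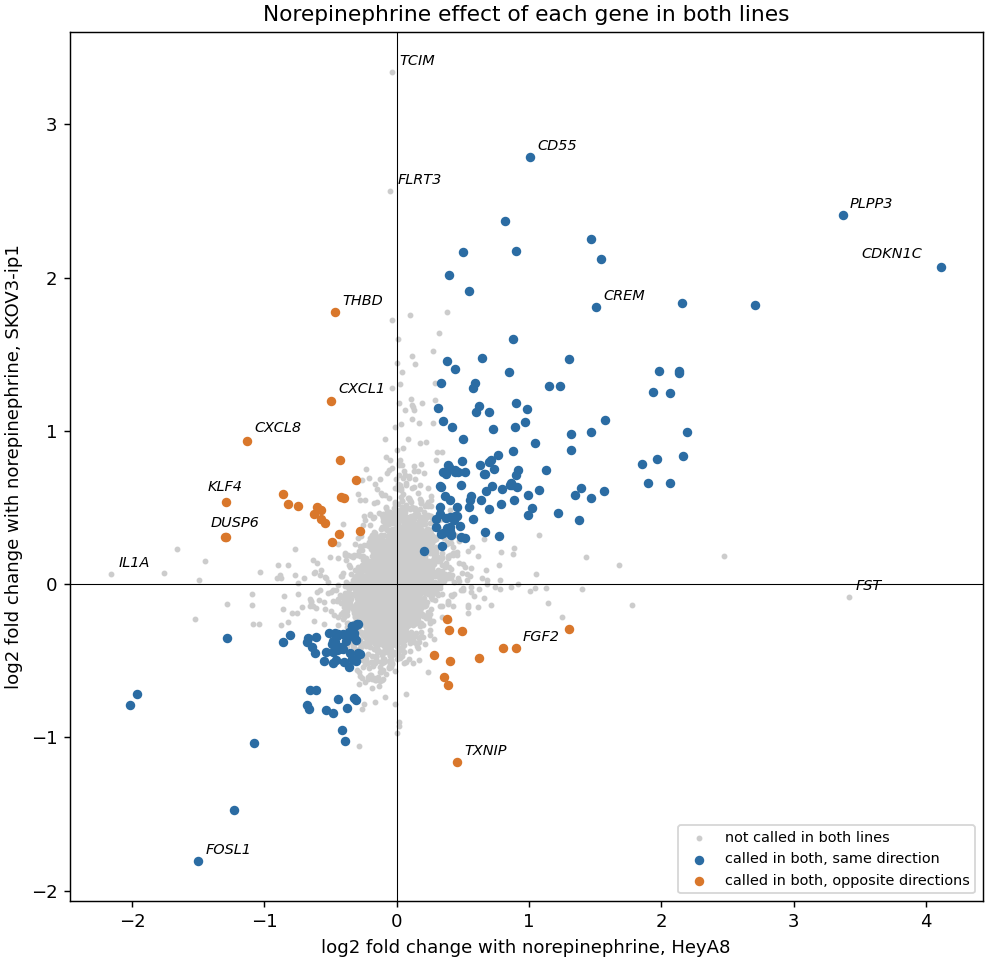
Log2 fold change with norepinephrine in HeyA8 (x) against SKOV3-ip1 (y), 1 point per gene tested, blue where called in both lines in the same direction, orange where called in opposite directions, and grey otherwise. The 190 genes called in the same direction include CDKN1C (4.12 and 2.07) and FOSL1 (-1.50 and -1.81), and the 33 in opposite directions include CXCL8 (-1.13 and 0.94).

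The difference between both effects asked where the lines responded differently. FST rose in HeyA8 and stayed at a low level in SKOV3-ip1 (5.92 with norepinephrine; difference 3.50 ± 0.18, adjusted p = 1.2e-11). TCIM rose in SKOV3-ip1 and stayed under the 40th percentile in HeyA8 (1.77e-14). NID2 (4.42e-11), CDKN1C (2.05 ± 0.14) and DUSP10 (1.92 ± 0.16), a phosphatase of stress kinases, had the more positive effect in HeyA8. FLRT3 (1.61e-13), the anticoagulant receptor THBD (1.73e-10), IL1A (-2.22 ± 0.13) and CXCL8 (-2.07 ± 0.14, 1.45e-09) had the more positive effect in SKOV3-ip1. The sizes for TCIM, NID2, FLRT3 and THBD, which lay under the 40th percentile in at least 1 group (THBD on average only), depend on the pseudocount. CDKN1C (5.70) and DUSP10 (5.66) lay close to the mean 40th percentile of HeyA8 control (5.645), so their sizes depend in part on the pseudocount. IL1A lay at 5.88 to 5.91 on the SKOV3-ip1 control arrays, close to their 40th percentiles (5.64 to 5.66). A fall as large as that in HeyA8 could not have been read there, so its difference depends in part on the low level in untreated SKOV3-ip1. In all, 171 genes had the more positive effect in HeyA8 and 261 in SKOV3-ip1, of which 81 and 158 differed at least 1.5-fold.

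Inflammatory cytokines and chemokines differed as a list, with 7 of 17 members more negative in HeyA8, 1 more positive and 9 not passing (8 and 3 adjusted over the list alone; 0.0013, adjusted p = 0.073 with an estimated correlation, 0.153 with no filter and 0.0981 with the mean of all probe sets). Among them were CXCL1 (-1.69 ± 0.17) and CXCL2 (-1.24 ± 0.13). The unfolded protein and amino acid stress response was more positive in SKOV3-ip1, with 8 of 27 members and 0 the other way (9 and 0 adjusted over the list alone; 0.000885, and 0.03 with an estimated correlation). Among these were HERPUD1 (-0.96 ± 0.17), DNAJB9 (-0.91 ± 0.19) and TRIB3 (-0.76 ± 0.12). Cell cycle genes were more negative in SKOV3-ip1, with 5 of 38 members and 1 the other way (10 and 1 adjusted over the list alone; 0.00101, and 0.03 with an estimated correlation). The difference was 0.77 ± 0.12 for PLK1 and, the other way, CDC6 had -0.88 ± 0.12. Heat shock genes were more positive in HeyA8, with 4 of 15 members and 0 the other way (4 and 0 adjusted over the list alone; 0.0433, adjusted p = 0.511 with an estimated correlation). This call ended without HeyA8 control 2 (0.06), HeyA8 norepinephrine 2 (0.0523), SKOV3-ip1 control 2 (0.0687) or 3 (0.101), or SKOV3-ip1 norepinephrine 1 (0.212) or 3 (0.0773). It also ended with the smaller pseudocount (0.0509) or none (0.0513), with no filter (0.0835) or one at the 60th percentile (0.102), and with all 15 arrays in 1 fit (0.0516).

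Members of uncalled lists also differed. Of the cAMP/CREB targets, 8 of 28 were more positive in HeyA8 and 11 in SKOV3-ip1 (0.534). The latter included KLF4 (-1.83 ± 0.16), PDE4D (-1.55 ± 0.21), SIK1 (adjusted p 6.86e-07) and NR4A2 (adjusted p 7.36e-05). The sizes for SIK1 and NR4A2 depend on the pseudocount in the same way. Among angiogenesis factors, FGF2 (1.32 ± 0.11), ADM (1.22 ± 0.13) and EDN1 (1.15 ± 0.12) were more positive in HeyA8. The effects on CREM (-0.30 ± 0.12, 0.209), IL6 (-0.71 ± 0.25, 0.138), VEGFA (0.33 ± 0.18, 0.416) and MMP2 (0.32 ± 0.12, 0.175) did not pass as different.

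Without treatment, the lines differed in 4769 of 8454 genes, 2242 higher in HeyA8 and 2527 higher in SKOV3-ip1, and 982 and 1035 of these differed at least 1.5-fold. HeyA8 had far more IL13RA2, a decoy receptor of interleukin-13 (at least 37.8-fold, adjusted p = 2.77e-23), the proteoglycan SRGN (at least 34.4-fold) and the collagen-modifying enzyme PLOD2 (2.39e-21). SKOV3-ip1 had far more of the calcium-binding proteins CALB1 (at least 46.2-fold) and S100A4 (-6.21 ± 0.09), keratin KRT19 (at least 52.1-fold) and NID2 (at least 43.8-fold). ERBB2, the receptor gene amplified in SKOV3, was lower in HeyA8 (-3.70 ± 0.11, 1.1e-17).

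As a list, ovarian carcinoma markers were lower in HeyA8, 14 of 18 members and 0 higher (14 and 0 adjusted over the list alone; 2.45e-05, and 0.0189 with an estimated correlation). Values were SLPI -3.39 ± 0.14, L1CAM at least 5.11-fold lower and LCN2 -1.81 ± 0.10, beside ERBB2. p53 targets and apoptosis were higher in HeyA8, 15 of 20 members and 2 lower (15 and 2 adjusted over the list alone; 1.29e-05, and 0.0189 with an estimated correlation). These included the death receptor FAS (3.33 ± 0.12), the cell cycle inhibitor CDKN1A (2.86 ± 0.14) and ZMAT3 (2.18 ± 0.13). With the preset correlation alone, epithelial markers were lower in HeyA8 (11 of 15 lower, 2 higher; 11 and 2 adjusted over the list alone; 0.000696, adjusted p = 0.0525 with an estimated correlation). Desmoplakin DSP and SPINT2 were both at -3.51 and CD24 at -3.19 ± 0.13. Mesenchymal markers were higher (10 of 15 higher, 3 lower; 10 and 3 adjusted over the list alone; 0.0245, adjusted p = 0.108 with an estimated correlation, 0.0504 with no filter and 0.0697 with all 15 arrays in 1 fit). LOX (2.56e-16) was higher and S100A4 and TAGLN (at least 8.46-fold) were lower. Interferon response genes were lower (12 of 26 lower, 2 higher; 12 and 2 adjusted over the list alone; 0.0245, adjusted p = 0.248 with an estimated correlation, 0.108 with no filter and 0.111 with all 15 arrays in 1 fit). Ribosomal proteins were higher (17 of 37 higher, 2 lower; 17 and 1 adjusted over the list alone; 0.0245, adjusted p = 0.191 with an estimated correlation, and 0.0883 with quantile normalization). Inflammatory cytokines and chemokines had 6 of 17 higher and 4 lower and were not called (0.123). CXCL8 (2.70 ± 0.10), IL1A (2.68 ± 0.09) and CXCL1 (2.61 ± 0.12) were all higher in HeyA8.

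Each line was also set against normal ovary, which the labels give as a control tissue; a line and a tissue can differ in cell type as well. The collagen gene COL3A1 was at least 91.9-fold lower in HeyA8 and 91.8-fold lower in SKOV3-ip1 (adjusted p = 3.5e-21 and 3.45e-21), the collagen gene COL1A1 at least 94.6-fold and 94.5-fold, and periostin (POSTN) at least 39.0-fold in both. IL6 was lower in both (-6.46 ± 0.17 and -6.18 ± 0.17). Its level was 12.27 ± 0.06 in normal ovary against 5.81 ± 0.52 in HeyA8 and 6.09 ± 0.24 in SKOV3-ip1. VEGFA changed by -4.65 ± 0.14 and -3.18 ± 0.14. IL13RA2 (at least 37.1-fold), G0S2 (5.83 ± 0.11), a regulator of lipolysis, and PLAU (at least 30.7-fold) were among the genes higher in HeyA8. S100A2 (6.56 ± 0.10), CALB1 (at least 45.3-fold) and S100A4 (6.12 ± 0.10) were among those higher in SKOV3-ip1. HeyA8 had 2759 genes higher and 2387 lower of 8473, and SKOV3-ip1 2883 higher and 2088 lower. Of these, 1495, 1162, 1446 and 1036 changed at least 1.5-fold.

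The same 6 lists were lower in both lines, with both correlations (adjusted p 0.00328 to 0.0217 with an estimated correlation). Inflammatory cytokines and chemokines had 18 of 23 members lower in HeyA8 and 0 higher (18 and 0 adjusted over the list alone; 7.93e-10) and 19 lower and 1 higher in SKOV3-ip1 (19 and 1 adjusted over the list alone; 1.95e-13). CCL2 was at least 18.9-fold lower in both and the NF-kB inhibitor TNFAIP3 changed by -4.56 and -4.19. Interferon response had 28 of 30 lower and 0 higher in HeyA8 (28 and 0 adjusted over the list alone; 1.2e-10) and 23 lower and 3 higher in SKOV3-ip1 (23 and 3 adjusted over the list alone; 5.17e-07). The transcription factor IRF1 changed by -3.37 and -3.12 and the antigen-presenting HLA-B by -2.82 and -1.73. The unfolded protein and amino acid stress response had 24 of 28 lower and 1 higher in HeyA8 (24 and 1 adjusted over the list alone; 2.27e-07) and 21 lower and 4 higher in SKOV3-ip1 (21 and 4 adjusted over the list alone; 2.23e-07). Asparagine synthetase ASNS changed by -2.73 and -2.86. Mesenchymal markers had 12 of 19 lower and 3 higher in HeyA8 (12 and 3 adjusted over the list alone; 6.39e-05) and 14 lower and 4 higher in SKOV3-ip1 (15 and 4 adjusted over the list alone; 5.17e-07). Glycolysis and hypoxia targets had 18 of 30 lower in both and 5 and 6 higher (18 and 5, and 18 and 7, adjusted over the list alone; 7.65e-05 and 0.000128). DDIT4 was at least 20.3-fold lower in HeyA8 and changed by -3.62 in SKOV3-ip1. cAMP/CREB targets had 18 of 28 lower and 5 higher in HeyA8 (18 and 5 adjusted over the list alone; 3.74e-05) and 17 lower and 7 higher in SKOV3-ip1 (18 and 7 adjusted over the list alone; 0.000408). The transcription regulator ID2 was at least 30.9-fold lower in HeyA8 and changed by -2.93 in SKOV3-ip1.

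Further lists were called in 1 of the lines. p53 targets and apoptosis were higher in HeyA8, 15 of 20 members and 1 lower (15 and 1 adjusted over the list alone; 0.00208, and 0.033 with an estimated correlation). The kinase PLK2 was at 3.10 ± 0.12, and the list was not called in SKOV3-ip1 (6 higher, 10 lower; 0.19). Ovarian carcinoma markers were higher in SKOV3-ip1, 11 of 18 members and 2 lower (11 and 2 adjusted over the list alone; 0.00183, and 0.0331 with an estimated correlation). They included MECOM (at least 19.2-fold), osteopontin SPP1 (at least 9.92-fold), ERBB2 (3.50 ± 0.10) and PAX8 (2.47 ± 0.14). The list was not called in HeyA8 (5 higher, 4 lower; 0.991). Ovarian stroma and steroidogenic markers were lower in SKOV3-ip1, 5 of 8 members and 0 higher (5 and 0 adjusted over the list alone; 0.00183, and 0.0451 with an estimated correlation), with the proteoglycan decorin DCN at least 10.1-fold lower. That call ended with no filter (0.0985) and with 1 normal ovary array left out, whichever it was (0.195 to 0.305). In HeyA8, 4 of 8 were lower and 2 higher, and the list was not called (0.2).

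Other calls against normal ovary rested on the preset correlation alone. Cell cycle genes had 22 of 38 higher in both lines and 7 and 8 lower (22 and 8 in both adjusted over the list alone; 0.0308 and 0.0367, adjusted p = 0.0808 and 0.0877 with an estimated correlation), with CDC20 at 1.61 and 1.97. The calls ended with 1 normal ovary array left out (0.0547 and 0.0534), with quantile normalization (0.0677 and 0.0649) and with the filter at the 60th percentile (0.0773 and 0.0518). TGF-beta targets had 10 and 11 of 18 lower and 3 and 4 higher (the same adjusted over the list alone; 0.0303 and 0.0326, adjusted p = 0.258 and 0.224 with an estimated correlation; 0.0569 and 0.0742 with the mean of all probe sets, and 0.0567 in HeyA8 with the filter at the 60th percentile). ID3 changed by -3.50 and -4.20. Cholesterol biosynthesis had 10 of 16 higher and 0 lower in HeyA8 (10 and 0 adjusted over the list alone; 0.00259, adjusted p = 0.117 with an estimated correlation), with SQLE at 2.15 ± 0.08. In SKOV3-ip1, epithelial markers had 9 of 15 higher and 3 lower (9 and 3 adjusted over the list alone; 0.0358, adjusted p = 0.0976 with an estimated correlation; 0.164, 0.151 and 0.159 without control 1, 2 and 3, and 0.0559 with the larger pseudocount). Ribosomal proteins had 19 of 37 lower and 6 higher (19 and 7 adjusted over the list alone; 0.0361, adjusted p = 0.118 with an estimated correlation, 0.0521 without control 3 and 0.0997 with quantile normalization). Immune cell markers had 3 of 8 lower and 0 higher in both lines, smooth muscle and endothelial markers 2 and 1 of 7 higher, and blood and erythroid markers 0 of 4 passing. None of these lists was called. RPL38 was uncertain in HeyA8 against normal ovary, since its called probe sets pointed in opposite directions, and its call ended with 1 normal ovary array left out (0.0917) and with the mean of all probe sets (0.142).

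**Figure D5:**
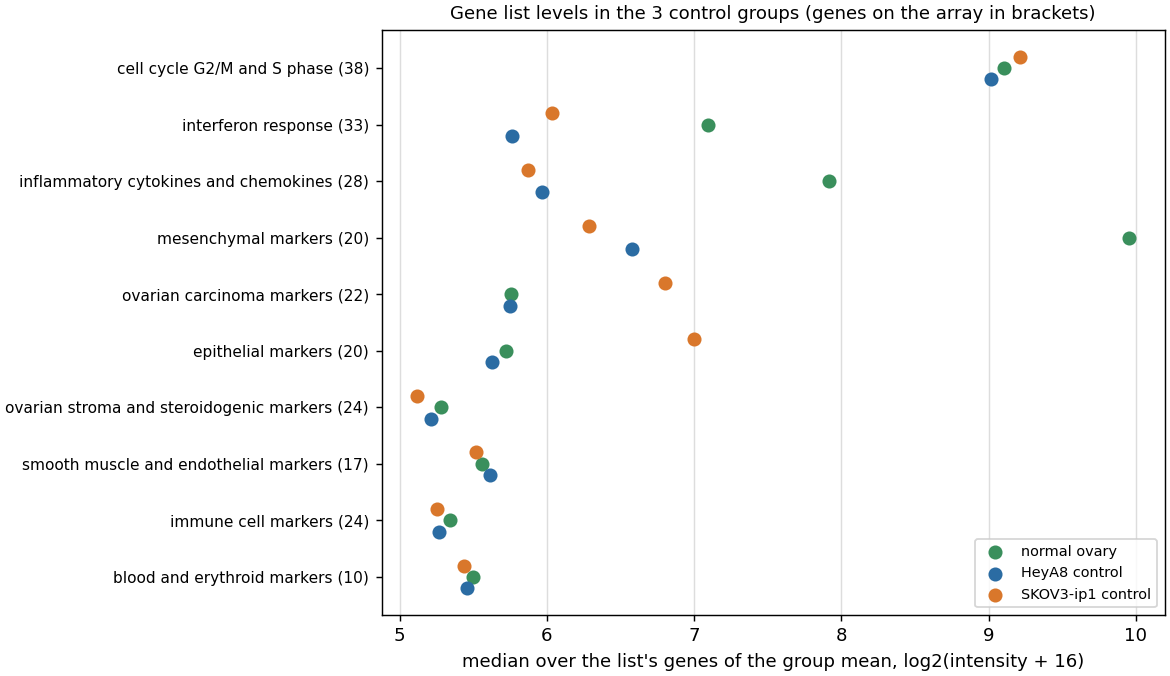
Median over list members of the group mean of log2(intensity + 16) for 10 gene lists in the 3 control groups, with the number of list genes on the array in brackets. Mesenchymal markers lay at 9.95 in normal ovary, 6.58 in HeyA8 and 6.28 in SKOV3-ip1, while immune cell markers lay at 5.34, 5.27 and 5.26.

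Of 3798 genes called in both lines against normal ovary, 1798 were higher and 1417 lower in both, and 583 moved in opposite directions. Independent lists would share 939 and 588, and simulated unchanged groups against the same 3 normal ovary arrays shared 0 calls. With no gene changed, few calls are made at an adjusted p under 0.05. The 0 therefore cannot tell how much of the overlap comes from the shared arrays. The log2 fold changes correlated at r = 0.665 across genes, against 0.503 in the simulation, with a covariance of 0.484 against 0.00476. Since both comparisons use the same 3 normal ovary arrays, which are too few to split, part of the excess over independent lists may come from the shared controls.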

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

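Of the tests in this part, only that of ERK targets in the difference between lines was chosen after the result was seen. The patterns themselves had been seen when the other tests were written, and the tests of the between-array normalization were reworded to genes of similar brightness before they were run.

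The norepinephrine effect differed between HeyA8 and SKOV3-ip1 in 432 genes by the test of the difference itself, and in 81 of the 151 genes named for the norepinephrine comparisons. Effects in HeyA8 minus those in SKOV3-ip1 were 3.50 for FST, 2.29 for NID2, 2.05 for CDKN1C, 1.92 for DUSP10 and 1.62 for TXNIP on the log2 scale. The fitted sizes for NID2, TCIM, FLRT3, NR4A2, FOS and THBD depend on the pseudocount and are no measured folds, since a group lay under the 40th percentile (THBD on average only), and the 3 SKOV3-ip1 control values of CDKN1C were exactly equal. CDKN1C and DUSP10 lay close to the 40th percentile in HeyA8 control, so their sizes depend in part on the pseudocount as well. Differences were -3.38 for TCIM, -2.61 for FLRT3, -2.24 for THBD, -2.22 for IL1A, -2.07 for CXCL8 and -1.25 for NR4A2. IL1A lay just above the 40th percentile in untreated SKOV3-ip1, so a fall as large as that in HeyA8 could not have been read there. For FOS the difference was -0.64 (adjusted p = 0.0185). That call ended without HeyA8 control 2 (0.0705) or 3 (0.0549), HeyA8 norepinephrine 1 (0.0583) or SKOV3-ip1 norepinephrine 1 (0.0538), and with a pseudocount of 1 (0.0604) or none (0.0678). As lists, inflammatory cytokines and chemokines (adjusted p 0.0013), cell cycle genes (0.00101), the unfolded protein and amino acid stress response (0.000885) and the heat shock response (0.0433) differed between the lines. For the inflammatory and heat shock lists, adjusted p = 0.073 and 0.511 with an estimated correlation. Among 1581 tested probe sets that name no gene or several, which the comparisons did not use, norepinephrine called 61 in HeyA8 and 118 in SKOV3-ip1.

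The first pattern weighed was that 33 genes called in both lines moved in opposite directions with norepinephrine, among them CXCL8, CXCL1, CXCL2, KLF4, THBD and TXNIP (2 of the 33, DUSP6 one of them, lay under the 40th percentile in both groups of a line, so their opposite direction is uncertain). The count of 33 alone is no excess, since independent lists of the sizes called would share about as many in opposite directions. An unreliable probe set as the cause could be checked only for 14 of the 33 genes, which had another tested probe set. Of these 21 other probe sets, 19 (90.5%) gave a difference between the lines of the same sign. For the 14 genes this argues against a difference that rests on an unreliable probe set. It does not show opposite movement, since a probe set that is flat in either line can keep the sign. For the rest of the 33 genes, CXCL1 and CXCL2 among them, an unreliable probe set was not tested and stays open. The between-array normalization cannot be told apart as a cause: in 100% of the 33 genes, the 200 genes nearest in brightness moved by at most 10.8% of the gene's own change, but arrays with nearly equal quantiles centre such genes near 0 in any case. A candidate explanation that stays open as a hypothesis is that the lines differ in how norepinephrine acts on ERK signalling, since ERK feedback and target genes without the 33 genes were lower in the HeyA8 effect minus the SKOV3-ip1 effect (14 genes, camera p = 0.0347 with an estimated correlation). Other differences between the lines, such as receptors, culture or exposure, were not tested as causes of this pattern.

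The second pattern was the fall of cell cycle genes with norepinephrine in SKOV3-ip1, where the fall of PLK1 had been seen before the tests were written. The between-array normalization cannot be told apart as a cause, since the 0.0146 by which genes nearest in brightness to the members moved on average (list median -0.17) is held near 0 by arrays with nearly equal quantiles. A single array is argued against, since the largest camera p with 1 of the 6 SKOV3-ip1 arrays left out was 3.6e-05 with the preset correlation and 0.00598 with an estimated one, not adjusted over lists. A lower share of cycling cells alone had been predicted to lower S-phase and mitotic genes alike. The mitotic median lay 0.27 lower than the S-phase median instead (-0.271, one-sided permutation p = 9e-05 over 100000 permutations of the member labels). The permutations treat genes as independent. Whether fewer cycling cells lower both sets by equal amounts was not tested, so this gap does not exclude a lower share of them. A change in passage through G2 and mitosis in this line stays open as well. It may follow from norepinephrine and was not measured here.

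Other splits of the same arrays were refitted for each comparison. The average over both lines called 1267 genes, and 1 of 100 splits, the real one, called as many. The highest other called 432 and exchanged the treatment labels in 1 line. The share lies under the 0.05 set in advance, which argues against a chance split of these arrays as far as they are independent. The labels do not say whether replicates were separate cultures. The difference between lines called 432 genes, and 2 of 100 splits called as many. These were the real one and the one with labels exchanged in 1 line, which equals the average and called 1267. The rest called at most 301. Such splits exchange treatment labels within the lines, so an effect shared by both lines enters them as well. They therefore cannot decide whether the difference between lines arose by chance. For the other comparisons, 10 splits are too few for a share under 0.05: norepinephrine in HeyA8 called 490 and the highest other split 1, norepinephrine in SKOV3-ip1 1169 and 2, HeyA8 control against SKOV3-ip1 control 4769 and 0, HeyA8 against normal ovary 5146 and 0, and SKOV3-ip1 against normal ovary 4971 and 0.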

How the results depend on the processing

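All tests with the alternatives were planned except the one with no pseudocount, which was chosen after seeing the data. Counts of calls stayed within 1.5 times under quantile normalization, median centring, all pseudocounts, both filters, both ways of using several probe sets, both other spread models and all 15 arrays in 1 fit. Leaving out 1 array gave 366 to 409 genes for norepinephrine in HeyA8 (490 with all arrays), 854 to 1233 in SKOV3-ip1 (1169), 1011 to 1313 for the average (1267), 319 to 491 for the difference (432), 4389 to 4577 between the control lines (4769), 4684 to 4812 and 4535 to 4784 for HeyA8 and SKOV3-ip1 against normal ovary (5146 and 4971), and 151 to 201 and 2876 to 3176 for the overlaps with norepinephrine and against normal ovary (190 and 3215). A 1.5-fold minimum, which adds a criterion, left 179, 222, 153, 239, 2017, 2657 and 2482 genes and overlaps of 71 and 1458, in the same order. With only the groups compared, norepinephrine in SKOV3-ip1 called 709 genes (the cause was not tested). The main fit gave each gene 1 spread for both lines. The median gene SD was 0.104 and 0.0977 in SKOV3-ip1 (control and norepinephrine), and 0.0754 and 0.074 in HeyA8. Of 168 list tests 56 were called, against 32 with an estimated correlation and 119 with fry, which are other tests. Reversed were NR4A1 with the mean of all probe sets (0.19 in HeyA8, adjusted p 0.0476, and 0.17 on average, adjusted p 0.00509, both passing), which takes other probe sets, and, with fry in HeyA8 against normal ovary, the test direction (not the medians, which are the same) of matrix proteases and inhibitors (-0.0344), focal adhesion and Src signalling (-0.0518) and ovarian carcinoma markers (-0.0128), higher with fry and lower but not called with camera. With the replicate number as a block the counts were 443, 1090, 1166, 404, 3811, 5196 and 5033, overlaps 168 and 3263, and 57 lists; for SKOV3-ip1 against normal ovary, the only pairing over 0.1 in every pair, each array correlated best with its own number and no named call changed, while the norepinephrine pairs lay between -0.22 and 0.097. Leaving out 1 array gave 235 weaker, 17 stronger, 36 moved and 0 reversed among the values of named genes. Signal over background limits the named genes that lay under the 40th percentile in 1 group, whose sizes moved with the pseudocount (TCIM in SKOV3-ip1 4.57 with none). Scaling moved the median of all genes by under 0.1.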

Other observations

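Of the tests in this part, both on the normal ovary arrays were chosen after the result was seen. Those on ERK, YAP/TEAD and FOXO targets in the average of both lines were written before their values were known. The leading norepinephrine genes had been seen by then.

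Of 9 histone genes tested, 5 were higher in HeyA8 than in SKOV3-ip1 without treatment and 2 lower. H2BC12 was at 3.34 ± 0.10 and H2BC5 at 1.68 ± 0.10, and the list was not called (adjusted p 0.111). Oxidative phosphorylation split evenly between the untreated lines, with 14 of 42 members higher in HeyA8 and 14 lower, led by NDUFA9 at 1.64 ± 0.08 and NDUFB2 at -1.42 ± 0.07. Matrix proteases and inhibitors had 5 of 22 higher in HeyA8 and 9 lower. PLAUR (2.06 ± 0.13) and PLAU (2.03 ± 0.07) were higher and the collagenase MMP1 (at least 6.28-fold) and the matrilysin MMP7 (at least 3.41-fold) were lower. The endothelial receptor TIE1 was at least 7.44-fold higher in HeyA8 than in SKOV3-ip1 and at least 7.31-fold higher than in normal ovary, and endoglin ENG was higher by 2.89 ± 0.10 and 2.98 ± 0.12. Heat shock response had 9 of 15 members higher in each line than in normal ovary, with HSPH1 at 1.65 ± 0.09 in HeyA8 and 1.97 ± 0.09 in SKOV3-ip1, while HSPB1 was lower (-1.88 ± 0.09 and -0.98 ± 0.09), and the list was called in neither.

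The normal ovary arrays carried little signal of blood, immune, smooth muscle and endothelial cells, the third pattern weighed. Over 51 markers on the array from these 3 lists, normal ovary lay at a median of -0.00934 relative to the mean of both lines on the log2 scale, and 0 markers lay at least 1 unit higher there than in both lines, which argues against whole ovary tissue with its vessels and blood cells. Of the cell cycle list, 97.4% (37 of 38 genes) lay above the 60th percentile in all 3 normal ovary arrays, as many as in each line, and together with the high COL1A1 and COL3A1 this is in line with cultured dividing stromal or surface cells as a candidate source. The labels give ovary as the tissue and name no culture, so this remains a hypothesis, and it bears on what each line was compared with.

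Beyond the cAMP list, the genes that moved with norepinephrine raised 3 hypotheses, each tested as a list with limma's camera and an estimated correlation on the average of both lines. These camera p-values come from a model over 12 arrays and are not exact or permutation tests. ERK feedback and target genes, proposed to be lower, were lower with a camera p of 0.0476 (17 genes), but 0.0714 adjusted over the 3 lists and 0.133 without the 1 member already seen, so this test leaves an effect on ERK open. No prediction had been written for single lines, and the lists there kept the members already seen (1 ERK and 3 FOXO genes). These single-line values are thus a description and no independent support. With adjusted p of camera over the 3 lists, ERK targets were lower in HeyA8 (0.00508) and not called in SKOV3-ip1 (0.622). YAP/TEAD targets were higher in HeyA8 (0.0407) and not called in SKOV3-ip1 (0.109), and FOXO targets were higher in HeyA8 (0.0407) and not called in SKOV3-ip1 (0.895). YAP/TEAD target genes, proposed to be lower, lay higher instead (23 genes, camera p of 0.0216, 0.0648 adjusted over the 3 lists), which argues against lower YAP/TEAD activity in these samples as far as these genes report it. FOXO target genes, proposed to be higher, gave a camera p of 0.461 (12 genes), and 0.00727, higher, without the 3 members already seen. It had been written in advance that a p at or over 0.05 would exclude the ERK or FOXO hypothesis. The ERK list met its written criterion (lower, camera p of 0.0476). The adjustment and the removal of the seen member, which that criterion did not hold, took its p over 0.05. The FOXO list did not meet its criterion. Reading such a p as exclusion was given up after the values were seen, because it was wrong. Such a p does not show that a list did not move, and the FOXO value depended on 3 genes. The ERK and FOXO hypotheses may still hold and these data do not settle them.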
